A study of Homo sapiens with 12 samples.

How the data were processed

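Per the labels' protocols, the libraries were made with an Illumina TruSeq RNA kit from SW480 cells 20 h after treatment, and per the submitters' processing notes the reads were assigned to GRCh38. The estimated counts per Ensembl gene and per transcript were made by the authors and, as deposited, were not scaled between libraries. The TPM values per gene were computed by the authors. The aligner, the quantifier, the annotation release and the strandedness are not given in the sources used here. The labels give 0.1% DMSO for the control group, and the solvent content of the drug groups is not given in the sources used here. Reads were not analysed here, and the transcript TPM values were not used here.

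The gene table held 62703 gene IDs, of which 41737 had a symbol. GENCODE 29 on GRCh38 gave gene type, coordinates and gene GC content by Ensembl ID for 58279 of them. Estimated counts were rounded to whole numbers, genes were kept by edgeR's expression filter with the 4 groups, and libraries were scaled by the trimmed mean of M-values. One model with 4 group means was fitted to all 12 libraries, and 7 contrasts were tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 15684 genes kept. The SE of a log2 fold change was its absolute value over the root of the F statistic. CPM in the text used these scaled library sizes, and ± after a CPM is the SD of 3 libraries.

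The 32 gene lists and the settings of the tests were fixed before the data were examined. The lists were written from general knowledge and held 1032 symbols, of which 1030 were found. They covered cholesterol synthesis and uptake, fatty acid synthesis, lysosome and autophagy, the unfolded protein response, the integrated stress response, heat shock, NRF2 targets, ferroptosis defence, ferroptosis promotion, iron handling, metallothioneins, the mitochondrial genome, oxidative phosphorylation and glycolysis with hypoxia. They also covered G1/S, G2/M, replication histones, p53 targets, apoptosis control, pyrimidine and folate genes, ribosomal proteins, ribosome biogenesis, host genes of small nucleolar RNAs, NF-kB, interferon response, immediate early genes, Wnt targets, stem cell markers, epithelial genes, mesenchymal genes, and markers of blood cells and of fibroblasts with endothelium. Each list was tested by limma's camera with the preset correlation of 0.01 and again with a correlation estimated for each list, with Benjamini-Hochberg adjustment over the lists. Where a list passed both, mostly the adjusted p with the preset correlation is given, which can be far smaller than the other. Members of a list were counted by edgeR's test over all genes and again with the adjustment made over the list alone.

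Genes named for large changes were the 8 largest rises and the 8 largest falls at an adjusted p under 0.05 with a symbol, a mean of at least 5 CPM and no overlap between the libraries of the groups compared. List members named were among the 4 with the largest changes at a mean of at least 1 CPM. From these the report gives mainly genes whose call held with every single library left out. Genes that share reads with a readthrough, antisense or duplicate gene model were named as uncertain.

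Alternatives fixed with the lists were no expression filter, a filter of at least 1 CPM in 3 libraries, DESeq2's size factors (RLE) or library totals in place of the trimmed mean, the replicate number as a block, fits on the groups compared alone, a 2-fold minimum, DESeq2, limma on log2 TPM with pseudocounts of 1 and 0.1, limma's fry for the lists, and each library left out in turn. An offset per gene and library that removes each library's trend over GC content was added after the spread within groups had been seen to follow GC content. That offset was a natural spline with 5 degrees of freedom, also fitted with gene length and with the replicate block. The shared DMSO libraries of the single-drug comparisons were treated by 20 simulations in which the DMSO, salinomycin and 5-FU libraries were all drawn from the mean of the DMSO libraries with the fitted dispersions; these simulations were added after the overlap had been seen.

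The pipeline was tried on simulated counts shaped like the combination against DMSO. Without a GC trend in the simulation, edgeR recovered 61.2%, 86.6% and 98.5% of genes with log2 changes of 0.5, 1 and 2, and 2.75% of its calls were false. With a GC trend like the observed one it recovered 11.9%, 74.6% and 100%, with 1.56% false, and with the added offset 61.2%, 82.1% and 100%, with 4.84% false. The simulated trend was the same spline that the offset fits, and all simulated counts used the dispersions of the fit with that offset. The recovery with the offset was therefore built in and does not show how well the offset removes a real bias. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.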

Results

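RNA sequencing measured gene expression in SW480, a colorectal cancer cell line, after 20 h of treatment. The 4 groups of 3 libraries each received 0.1% DMSO as the solvent control, 2.5 µM salinomycin, 5 µM 5-fluorouracil (5-FU), or both drugs at these doses. Salinomycin is a polyether antibiotic that carries potassium ions across membranes, and 5-FU is a pyrimidine analogue that blocks thymidylate synthesis and is built into RNA. The estimated counts per library summed to between 18701104 and 21806318, and 15684 genes were tested. Expression is given as counts scaled to library size (CPM), and a change is the log2 fold change with its standard error (SE) from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Genes named for a large change between 2 groups were picked so that the libraries of the groups did not overlap. That rule was not applied to the interaction or to list members. For salinomycin against DMSO, 4293 of the 15684 genes met it. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Of 17 fixed markers of blood cells, 13 stayed under 1 CPM in every library, and so did 13 of 17 markers of fibroblasts and endothelium, where LUM was the highest at a mean of 20.2 CPM.

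The series title names SLC7A11, the cystine importer, and GPX4, the enzyme that removes lipid peroxides; loss of either is known to open the way to ferroptosis. SLC7A11 (ENSG00000151012, GRCh38 chromosome 4, 138164097 to 138242349, minus strand) had 18.5 ± 4.88 CPM with DMSO, 14.7 ± 3.17 with salinomycin, 12.9 ± 3.20 with 5-FU and 24.7 ± 4.92 with both drugs (SD, n = 3 each). Its log2 fold change against DMSO was -0.34 ± 0.23 with salinomycin, -0.52 ± 0.23 with 5-FU and 0.42 ± 0.23 with both, and none of these passed edgeR's test (adjusted p = 0.351, 0.142 and 0.248). With an offset for GC content these values were 0.01, -0.28 and 0.53, of which those with 5-FU (adjusted p = 0.0412; from 0.00778 to 0.608 over all settings) and with both drugs (0.000666; from 1.58e-05 to 0.53) passed. SLC7A11 rose 1.69-fold in the combination against salinomycin alone (log2 fold change 0.75 ± 0.23, edgeR adjusted p = 0.0425; from 0.000116 to 0.167 over all settings). That call was lost without salinomycin replicate 2 or 3 or combination replicate 1 or 3, and with limma. Against 5-FU alone it was 0.94 ± 0.23 higher on the log2 scale without passing edgeR's test (adjusted p = 0.0758). GPX4 (ENSG00000167468, GRCh38 chromosome 19, 1103926 to 1106791, plus strand) had 181 ± 34.4 CPM with DMSO, 241 ± 32.8 with salinomycin, 211 ± 37.4 with 5-FU and 191 ± 23.1 with both (SD, n = 3 each). No comparison passed edgeR's test for GPX4: against DMSO the log2 fold change was 0.41 ± 0.16 with salinomycin (adjusted p = 0.127), 0.22 ± 0.16 with 5-FU (0.357) and 0.08 ± 0.16 with both (0.773). In the combination GPX4 stood at -0.33 ± 0.16 against salinomycin (adjusted p = 0.168) and at -0.14 ± 0.16 against 5-FU (0.74). An offset for GC content brought the GPX4 value to 0.14 for salinomycin against DMSO, 0.03 for 5-FU against DMSO, -0.06 for the combination against salinomycin, 0.05 for the combination against 5-FU and -0.09 for the interaction. In every group at least 99.6% of the SLC7A11 counts lay on 1 transcript, and 1 transcript held between 92.2% and 92.8% of those of GPX4.

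**Figure D1:**
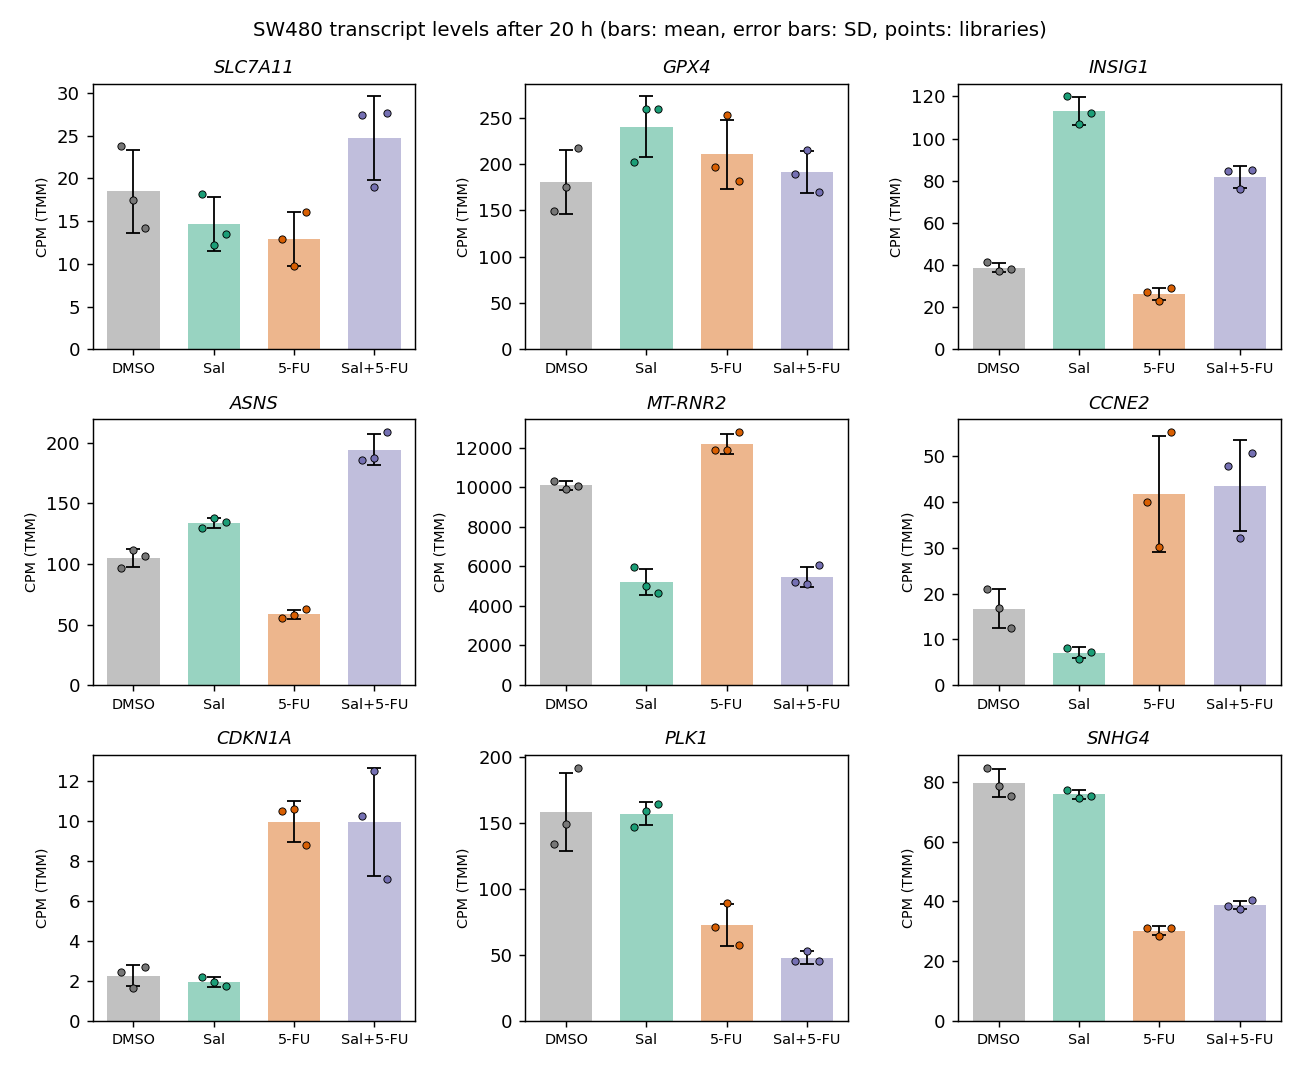
CPM of 9 genes in the 4 groups; bars are group means, error bars the SD of 3 libraries and points the single libraries. SLC7A11 had its highest group mean, 24.7 CPM, with both drugs, while ASNS went from 58.7 CPM with 5-FU to 194 CPM with both.

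Neither of the fixed ferroptosis lists was called by camera in any comparison without an offset for GC content. With that offset the genes that promote ferroptosis were called upward for salinomycin against DMSO (adjusted p = 0.0114) and for the combination against 5-FU (0.0157), and neither call held with an estimated correlation as well (adjusted p = 0.061 and 0.0743). Among 29 measured genes of ferroptosis defence, 1 rose and 1 fell with salinomycin (2 and 1 adjusted over the list alone), and 0 rose and 1 fell with 5-FU (0 and 1 adjusted over the list alone). With both drugs against DMSO 3 rose and 2 fell (3 and 2 adjusted over the list alone). The camera adjusted p was 0.18 with salinomycin, 0.985 with 5-FU and 0.51 with both. The desaturase SCD accounted for the rise with salinomycin (log2 fold change 0.62 ± 0.07) and for the fall with 5-FU (-0.39 ± 0.07). Among 21 genes that promote ferroptosis, 2 rose with salinomycin, 3 rose and 1 fell with 5-FU, and 4 rose with both drugs (3, 3 and 1, and 4 adjusted over the list alone; camera adjusted p = 0.0512, 0.742 and 0.245). HMOX1, which releases iron from haem, rose with 5-FU (log2 fold change 1.27 ± 0.18), and TFRC, the transferrin receptor, fell with it (-0.82 ± 0.14). The 24 measured genes of iron handling gave camera adjusted p of 0.673, 0.461 and 0.542 against DMSO, with 0, 7 and 4 members past edgeR's test and 0, 7 and 5 adjusted over the list alone.

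The first comparison asked what salinomycin alone changed. Salinomycin raised genes of sterol and fatty acid synthesis, of the lysosome and of the stress pathways of the endoplasmic reticulum, and lowered genes of DNA replication. INSIG1, the sterol-sensing anchor of SCAP (ENSG00000186480, GRCh38 chromosome 7, 155297776 to 155310235), rose 2.91-fold, from 38.8 to 113 CPM. LSS and MVD, both enzymes of cholesterol synthesis, each rose 2.51-fold, the lysosomal sialidase NEU1 rose 2.59-fold and the stress cytokine GDF15 rose 2.84-fold. The growth factor carrier FGFBP1 rose 2.98-fold, and IGFL2-AS1 rose 3.49-fold, although reads of this antisense gene cannot be told from those of its partner because strandedness is not given in the sources used here. The mitochondrial rRNAs MT-RNR1 and MT-RNR2 fell 2.05-fold and 1.94-fold, to 1345 ± 294 and 5206 ± 663 CPM (SD, n = 3), while MT-ND2 from the same genome rose 1.74-fold.

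Of 31 measured genes of cholesterol synthesis and uptake, 24 rose and none fell with salinomycin (24 and 1 adjusted over the list alone; median log2 fold change 0.79; camera adjusted p = 2.22e-48). Fatty acid synthesis had 11 of 25 members up (13 adjusted over the list alone; camera adjusted p = 2.56e-10). Among these were FASN at 1.12 ± 0.18 and ACSS2 at 1.07 ± 0.14. Lysosome and autophagy genes had 12 of 47 up (19 and 1 down adjusted over the list alone; camera adjusted p = 3.94e-10). Members included WIPI1 at 1.32 ± 0.11 and NPC2 at 0.79 ± 0.11. In the unfolded protein response 9 of 33 rose (13 adjusted over the list alone; camera adjusted p = 1.4e-09). Among these were HERPUD1, a part of protein degradation at the endoplasmic reticulum, at 0.95 ± 0.09. The integrated stress response, the programme run by ATF4, had 10 of 47 up (14 adjusted over the list alone; camera adjusted p = 2.24e-07, and adjusted p = 0.0656 with an estimated correlation). Members included INHBE at 1.29 ± 0.18, TRIB3 at 1.24 ± 0.16 and DDIT3 at 0.90 ± 0.12. Genes of G1/S and DNA replication had 17 of 48 down and none up (29 and 1 adjusted over the list alone; camera adjusted p = 1.62e-14). Among these were MCM10 at -0.80 ± 0.11 and CLSPN at -0.80 ± 0.12. Genes of G2/M had 6 of 40 down (18 adjusted over the list alone; camera adjusted p = 4.6e-07, and adjusted p = 0.0656 with an estimated correlation). Ribosome biogenesis had 6 of 53 down (17 adjusted over the list alone; camera adjusted p = 4.12e-05). With an estimated correlation, camera gave adjusted p of 0.0403 for this list and 0.0114 for lysosome and autophagy. It gave 4.68e-06 for cholesterol, 0.00313 for fatty acid synthesis, 0.00355 for the unfolded protein response and 0.000945 for G1/S. Of 23 genes that host small nucleolar RNAs 7 rose (12 adjusted over the list alone; camera adjusted p = 6.37e-06, and adjusted p = 0.199 with an estimated correlation). Of 56 ribosomal protein genes 2 rose (36 adjusted over the list alone; camera adjusted p = 4.31e-13, and adjusted p = 0.316 with an estimated correlation). NRF2 targets (median 0.21), immediate early genes (0.26), oxidative phosphorylation (0.18), glycolysis and hypoxia (0.14) and epithelial genes (0.20) were also called upward by camera, with adjusted p of 0.199, 0.316, 0.444, 0.382 and 0.382 with an estimated correlation. Genes of apoptosis control as a list did not stand apart (camera adjusted p = 0.42), although the p53 and stress target BBC3 rose 3.14-fold and BMF rose 2.04-fold, both of which promote cell death.

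edgeR's quasi-likelihood test called 719 genes at an adjusted p under 0.05 for salinomycin against DMSO, 397 higher and 322 lower. The slope of log2 counts over gene GC content, per 10 points of GC, averaged 0.139 ± 0.119 in the salinomycin libraries and -0.120 ± 0.210 in the DMSO libraries (SD, n = 3 each). Across genes, which are not independent replicates, the salinomycin change followed GC content with a Spearman rho of 0.598. Without DMSO replicate 1 or 2 or salinomycin replicate 2 or 3 the count was 142, 109, 126 or 109, and without DMSO replicate 3 it was 2956. A fit with an offset for GC content gave 2269 genes, 1088 higher and 1181 lower, which kept 649 of the 719, and ended the calls of the immediate early (adjusted p = 0.162), glycolysis (0.0853) and epithelial lists (0.0558), and with an estimated correlation as well that of ribosome biogenesis (0.231). It called heat shock genes (adjusted p = 0.00992) and Wnt targets (0.0391) downward, and neither passed with an estimated correlation as well (0.337 and 0.402).

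The second comparison asked what 5-FU alone changed. After 5-FU, cyclin E and inflammatory genes rose, while mitotic genes, replication histones and host genes of small nucleolar RNAs fell. CDKN1A, the inhibitor of cyclin-dependent kinases, rose 4.40-fold from a low level (2.26 to 9.99 CPM), and CCNE1, the cyclin of S-phase entry, rose 3.48-fold. The immediate early factor FOS rose 5.11-fold, the water and glycerol channel AQP3 rose 5.27-fold, the plasminogen activator PLAU rose 3.61-fold, WNT7B rose 3.75-fold, IGF2 rose 3.56-fold and KRT81 rose 3.50-fold. The helicase PIF1 had a log2 fold change of -2.14 ± 0.17, the mitotic kinesin KIF20A fell 2.75-fold, from 110 to 40.1 CPM, HMMR fell 3.31-fold, and SNHG4 fell 2.64-fold.

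In the G2/M list 22 of 40 members fell and 1 rose with 5-FU (25 and 1 adjusted over the list alone; median log2 fold change -0.48; camera adjusted p = 1.87e-17). Of 20 measured replication histones 8 fell (14 adjusted over the list alone; camera adjusted p = 6.66e-08). Members included H2BC5 at -1.40 ± 0.24 and H2BC12 at -1.25 ± 0.21; these mRNAs mostly lack long poly(A) tails. Of 23 host genes of small nucleolar RNAs 16 fell (17 adjusted over the list alone; camera adjusted p = 1.3e-14). One member was SNHG12 at -1.23 ± 0.13. In the G1/S list 20 of 48 rose and 1 fell (24 and 1 adjusted over the list alone; camera adjusted p = 3.8e-08). Members included E2F2 at 0.89 ± 0.16 and EXO1 at 0.80 ± 0.10. NF-kB and inflammation genes had 14 of 20 up (15 adjusted over the list alone; camera adjusted p = 2.81e-11). Among these were CCL20 at 1.56 ± 0.16, ICAM1 at 1.36 ± 0.14 and CXCL8 at 1.34 ± 0.23. Interferon response genes had 10 of 28 up and 1 down (15 and 1 adjusted over the list alone; camera adjusted p = 6.9e-08). An example was OAS1 at 1.07 ± 0.15, and p53 targets had 10 of 35 up (11 adjusted over the list alone; camera adjusted p = 0.000208). Among these were CD82 at 1.23 ± 0.15 and PLK2 at 1.12 ± 0.12. Mesenchymal genes had 11 of 21 up (13 adjusted over the list alone; camera adjusted p = 2.81e-11, and adjusted p = 0.0652 with an estimated correlation). One member was MMP14 at 1.22 ± 0.13. Pyrimidine and folate genes had 12 of 38 up (15 and 2 down adjusted over the list alone; camera adjusted p = 0.00213, and adjusted p = 0.229 with an estimated correlation). One member was the ribonucleotide reductase subunit RRM2 at 0.99 ± 0.07. The mitochondrial genome had 6 of 15 up and 1 down (9 and 1 adjusted over the list alone; camera adjusted p = 0.00322, and adjusted p = 0.446 with an estimated correlation). An example was MT-ND1 at 0.61 ± 0.11. Cholesterol genes had 7 of 31 down, with INSIG1 at -0.56 ± 0.10 (camera adjusted p = 0.0133, and adjusted p = 0.0572 with an estimated correlation). NRF2 targets (median 0.14), lysosome and autophagy (0.20) and immediate early genes (0.40) were called upward by camera, with adjusted p of 0.154, 0.152 and 0.421 with an estimated correlation. So were oxidative phosphorylation (adjusted p = 0.0338, and 0.694 with an estimated correlation), epithelial genes (0.042 and 0.409) and the few blood cell markers (0.014 and 0.1). Ribosome biogenesis (adjusted p = 0.0102, and 0.137 with an estimated correlation), ribosomal proteins (0.0222 and 0.694) and the integrated stress response (0.044 and 0.409) were called downward. Metallothioneins (camera adjusted p = 0.0785), Wnt and beta-catenin targets (0.0813) and stem cell markers (0.099) did not pass, nor did the unfolded protein response (0.669), fatty acid synthesis (0.641) and the ferroptosis lists.

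edgeR's quasi-likelihood test called 2857 genes for 5-FU against DMSO, 1657 higher and 1200 lower, so that 58.0% were higher; scaling by library totals alone gave 70.0%. The GC slope averaged 0.0583 ± 0.205 in the 5-FU libraries (SD, n = 3), and an offset for GC content raised the count to 5284, 2655 higher and 2629 lower, which kept 2715 of these genes. Without DMSO replicate 1 or 2 or 5-FU replicate 2 the count was 1400, 1422 or 1576, and the offset ended the calls of the immediate early list (adjusted p = 0.0855), the epithelial list (0.178) and the blood cell markers (0.0685). With the offset and an estimated correlation the host genes of small nucleolar RNAs did not pass (adjusted p = 0.0712). The offset called Wnt targets (adjusted p = 0.00641) and glycolysis (0.0239) downward and metallothioneins (0.0468) and apoptosis control (0.0468) upward, and none of these passed with an estimated correlation as well (0.316, 0.290, 0.358 and 0.122).

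The third comparison asked what both drugs together changed. The combination showed sterol, lysosomal and stress genes up along with cyclin E, p53 and inflammatory genes up, and mitotic genes, histones and ribosome biogenesis down. INHBE, a target of the integrated stress response, had a log2 fold change of 2.20 ± 0.18. GDF15 rose 3.80-fold, the amino acid exchanger SLC1A4 3.64-fold and ULBP1, a ligand for natural killer cells, 3.56-fold. CDKN1A rose 4.39-fold, FOS 4.16-fold and ANKRD22 3.85-fold. The mitotic kinase PLK1 fell 3.30-fold (159 to 48.1 CPM), KIF20A fell 3.29-fold, the mitotic activator CDC20 fell 3.06-fold, the prolyl hydroxylase EGLN3 fell 2.74-fold and the histone H2BC12 fell 2.84-fold. Values for BLOC1S5-TXNDC5 (log2 fold change 4.02 ± 1.10) and for an extra gene model of MKKS (ENSG00000285508, -2.10 ± 0.51) are uncertain, since both share reads with another gene model. The summed CPM of the MKKS models was 103 with DMSO and 104 with both drugs.

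In the G2/M list 27 of 40 members fell and none rose with both drugs (29 adjusted over the list alone; median log2 fold change -0.57; camera adjusted p = 2.86e-28). The integrated stress response had 19 of 47 up and 2 down (23 and 2 adjusted over the list alone; camera adjusted p = 6.19e-13). One member was NUPR1 at 3.19 ± 0.40 from a low level of 0.354 CPM. Cholesterol genes had 20 of 31 up and 1 down (24 and 1 adjusted over the list alone; camera adjusted p = 2e-13). Members included INSIG1 at 1.08 ± 0.10, ACAT2 at 1.04 ± 0.10 and IDI1 at 0.94 ± 0.13. The lysosome list had 13 of 47 up (15 adjusted over the list alone; camera adjusted p = 3.49e-09). Among these were WIPI1 at 1.81 ± 0.11 and GABARAPL1 at 1.07 ± 0.10. Fatty acid synthesis had 9 of 25 up (10 adjusted over the list alone; camera adjusted p = 2.3e-06). An example was ACSL1 at 0.96 ± 0.09, and the unfolded protein response had 12 of 33 up (15 adjusted over the list alone; camera adjusted p = 4.74e-07). One member was SEC24D at 1.10 ± 0.13. Of 20 replication histones 9 fell (13 adjusted over the list alone; camera adjusted p = 1.15e-09), and of 53 ribosome biogenesis genes 17 fell (22 adjusted over the list alone; camera adjusted p = 1.15e-08). Members included UTP20 at -0.96 ± 0.14 and BOP1 at -0.93 ± 0.20. Heat shock genes had 4 of 21 down and 1 up (10 and 1 adjusted over the list alone; camera adjusted p = 0.000403). One member was HSPA8 at -0.76 ± 0.08. G1/S genes had 14 of 48 up and 3 down (18 and 4 adjusted over the list alone; camera adjusted p = 0.000114), and p53 targets 11 of 35 up (14 adjusted over the list alone; 4.74e-07). NF-kB genes had 9 of 20 up (14 adjusted over the list alone; 5.42e-07) and interferon response genes 11 of 28 up and 1 down (13 and 1 adjusted over the list alone; 1.11e-05). Glycolysis and hypoxia genes had 11 of 39 down and 4 up, with SLC2A3 at -1.06 ± 0.09 (camera adjusted p = 7.42e-05, and adjusted p = 0.126 with an estimated correlation). Wnt and beta-catenin targets had 9 of 29 down and 3 up (13 and 6 adjusted over the list alone; camera adjusted p = 0.000742, and adjusted p = 0.0941 with an estimated correlation). Members included NKD1 at -0.87 ± 0.09 and AXIN2 at -0.64 ± 0.07. Apoptosis control had 7 of 34 up and 3 down, with the death activators BBC3 at 1.36 ± 0.21 and PMAIP1 at 1.05 ± 0.16 (camera adjusted p = 0.0293, and adjusted p = 0.0616 with an estimated correlation). Immediate early genes (median 0.47), NRF2 targets (0.16) and mesenchymal genes (0.18) were called upward by camera, with adjusted p of 0.128, 0.109 and 0.279 with an estimated correlation. So were the few measured markers of fibroblasts and endothelium, with 3 of 6 up (median 0.66; camera adjusted p = 0.0144, and adjusted p = 0.0616 with an estimated correlation), and of blood cells, with 1 of 4 up (median 0.58; camera adjusted p = 0.0144, and adjusted p = 0.0728 with an estimated correlation, or 0.0688 with an offset for GC content). Host genes of small nucleolar RNAs were called downward (median -0.27; adjusted p = 0.0941 with an estimated correlation). Stem cell markers had 2 of 17 up and 3 down (4 and 7 adjusted over the list alone; camera adjusted p = 0.245).

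edgeR's quasi-likelihood test called 2334 genes for the combination against DMSO, 1429 higher and 905 lower, so that 61.2% were higher; scaling by library totals alone gave 79.8%. The GC slope averaged -0.0773 ± 0.183 in the combination libraries (SD, n = 3), and an offset for GC content raised the count to 5282, 2602 higher and 2680 lower, which kept 2313 of these genes. Without combination replicate 1 or 2 or DMSO replicate 1 or 2 the count was 1308, 1534, 1503 or 1349. With the offset and an estimated correlation G1/S genes (adjusted p = 0.0624), ribosome biogenesis (0.0624) and heat shock (0.118) did not pass.

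**Figure D2:**
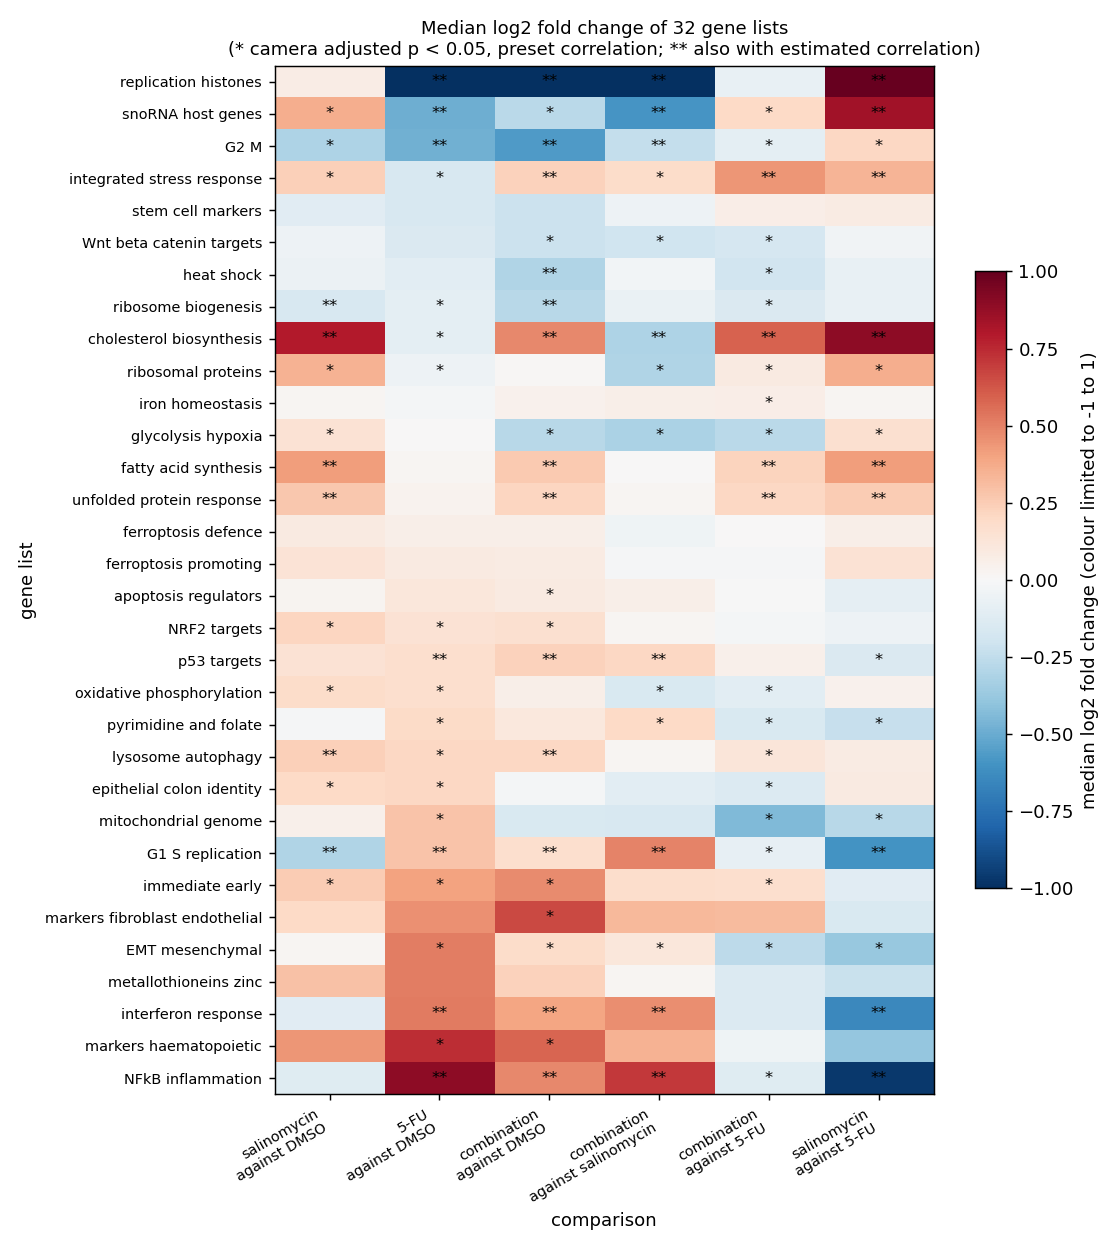
Median log2 fold change of 32 fixed gene lists (vertical) in 6 comparisons (horizontal), with colours limited to -1 and 1; 1 star marks a camera adjusted p under 0.05 and a second star a list that also passed with an estimated correlation. Cholesterol synthesis reached a median of 0.79 with salinomycin and 0.48 with both drugs against DMSO, and replication histones -1.01 with 5-FU.

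Adding 5-FU to salinomycin was tested by the combination against salinomycin. Cyclin E, p53 and inflammatory genes were higher with the added 5-FU, and mitotic genes, histones and snoRNA host genes were lower. CCNE2, the second cyclin E gene, rose 6.18-fold (7.06 to 43.6 CPM), CDKN1A rose 5.06-fold, the chemokines CXCL8 and CCL20 rose 4.14-fold and 3.34-fold, and the p53 relative TP73 rose 3.02-fold. CCNE2 had 16.7 CPM with DMSO, so part of its difference was a fall with salinomycin. PIF1 had a log2 fold change of -2.46 ± 0.18, the histone gene H2AW one of -1.98 ± 0.20, and PLK1 fell 3.27-fold.

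Of 48 G1/S genes 32 rose and none fell (36 and 2 adjusted over the list alone; median log2 fold change 0.49; camera adjusted p = 3.88e-25), with EXO1 at 1.25 ± 0.10. Host genes of small nucleolar RNAs had 18 of 23 down (19 adjusted over the list alone; camera adjusted p = 1.86e-18). One member was SNHG19 at -1.44 ± 0.20. Replication histones had 12 of 20 down (13 adjusted over the list alone; camera adjusted p = 6.99e-12) and G2/M genes 16 of 40 down and 2 up (18 and 3 adjusted over the list alone; 1.65e-10). NF-kB genes had 11 of 20 up (12 adjusted over the list alone; camera adjusted p = 1.49e-09), and interferon response genes 14 of 28 (15 and 1 down adjusted over the list alone; 3.52e-08). Targets of p53 had 8 of 35 up and 1 down (8 and 1 adjusted over the list alone; camera adjusted p = 0.00128). Cholesterol genes had 12 of 31 down (16 adjusted over the list alone; camera adjusted p = 1.57e-06). One member was LSS at -0.82 ± 0.15. Glycolysis and hypoxia genes had 17 of 39 down (20 adjusted over the list alone; camera adjusted p = 9.59e-10, and adjusted p = 0.0517 with an estimated correlation). Among these were EGLN3 at -1.15 ± 0.11 and the glucose carrier SLC2A1 at -0.78 ± 0.11. Ribosomal protein genes had 15 of 56 down (24 adjusted over the list alone; camera adjusted p = 5.33e-11, and adjusted p = 0.367 with an estimated correlation). An example was RPL3 at -1.03 ± 0.10. The integrated stress response had 13 of 47 up and 4 down (16 and 5 adjusted over the list alone; camera adjusted p = 0.0102, and adjusted p = 0.305 with an estimated correlation). One member was SLC1A4 at 1.78 ± 0.17. In all, camera called 15 lists here, 7 upward and 8 downward, and not all are described.

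edgeR's quasi-likelihood test called 2623 genes for the combination against salinomycin, 1388 higher and 1235 lower, so that 52.9% were higher; scaling by library totals alone gave 76.2% and moved the median of all genes by 0.12. The GC slope averaged -0.0773 ± 0.183 with both drugs and 0.139 ± 0.119 with salinomycin (SD, n = 3 each), and an offset for GC content gave 4532 genes, 2257 higher and 2275 lower, which kept 2393 of these with 1 in the opposite direction. Without salinomycin replicate 2 or 3 or combination replicate 1 or 3 the count was 1050, 1183, 1247 or 1222, and the call of SLC7A11 was lost (adjusted p = 0.167, 0.144, 0.135 and 0.144). The offset called immediate early genes upward (adjusted p = 0.000887) and the mitochondrial genome (0.00457) and ribosome biogenesis (0.000267) downward, and none of these passed with an estimated correlation as well (0.397, 0.540 and 0.379).

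Adding salinomycin to 5-FU was tested by the combination against 5-FU. Sterol genes and genes of the integrated stress response were higher with the added salinomycin, and mitochondrial rRNA was lower. ASNS, the asparagine synthetase (ENSG00000070669, GRCh38 chromosome 7, 97852118 to 97872542), rose 3.31-fold, from 58.7 to 194 CPM, INHBE rose 6.28-fold and ASS1, the argininosuccinate synthetase, rose 2.31-fold. INSIG1 rose 3.11-fold, HMGCS1, a synthase of the sterol pathway, rose 2.84-fold, and ULBP1 rose 2.93-fold. MT-RNR2 fell 2.23-fold, to 5457 ± 516 CPM (SD, n = 3). KRT81 had a log2 fold change of -1.17 ± 0.18, the protease KLK10 one of -1.31 ± 0.17 and the cytokine IL32 one of -1.40 ± 0.18.

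Of 31 cholesterol genes 13 rose and none fell (25 adjusted over the list alone; median log2 fold change 0.59; camera adjusted p = 2.54e-51), with MSMO1 at 1.04 ± 0.14. The integrated stress response had 20 of 47 up and none down (29 adjusted over the list alone; median 0.44; camera adjusted p = 1.1e-44), with ALDH1L2 at 1.73 ± 0.20. NUPR1 was also called, but no fold is given because it had 0.133 CPM with 5-FU. In the unfolded protein response 5 of 33 rose (7 adjusted over the list alone; camera adjusted p = 4.12e-11). An example was XBP1 at 0.65 ± 0.09, and in fatty acid synthesis 9 of 25 (10 and 1 down adjusted over the list alone), with ACSL1 at 0.74 ± 0.09 (2.3e-09). Iron handling had 2 of 24 up (2 adjusted over the list alone), of which TFRC rose at 0.84 ± 0.14 (camera adjusted p = 0.0404, and adjusted p = 0.104 with an estimated correlation). The mitochondrial genome had 7 of 15 down and 1 up (10 and 1 adjusted over the list alone; camera adjusted p = 2.34e-14, and adjusted p = 0.1 with an estimated correlation). One member was MT-CO3 at -0.78 ± 0.09. Mesenchymal genes had 4 of 21 down (7 adjusted over the list alone; camera adjusted p = 1.42e-08, and adjusted p = 0.104 with an estimated correlation). One member was PLAU at -0.72 ± 0.10. Host genes of small nucleolar RNAs had 3 of 23 up (9 adjusted over the list alone; camera adjusted p = 4.3e-06, and adjusted p = 0.14 with an estimated correlation). In all, camera called 21 lists here, 9 upward and 12 downward, and most of the downward ones are not described. With an estimated correlation 4 lists were called.

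edgeR's quasi-likelihood test called 210 genes for the combination against 5-FU, 149 higher and 61 lower, so that 71.0% were higher; scaling by library totals alone gave 79.8%. The GC slope averaged -0.0773 ± 0.183 with both drugs and 0.0583 ± 0.205 with 5-FU (SD, n = 3 each), and an offset for GC content gave 1254 genes, 624 higher and 630 lower, which kept 202 of the 210. Under that offset SLC7A11 was past edgeR's test (log2 fold change 0.81, adjusted p = 0.000142; from 2.44e-06 to 0.403 over all settings). Without 5-FU replicate 1 or 2 or combination replicate 1 or 3 the count was 93, 133, 101 or 125.

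The interaction asked whether the effect of salinomycin differed with and without 5-FU on the log scale. ASNS was the gene that passed: its salinomycin effect was 1.38 ± 0.12 larger with 5-FU than without (edgeR adjusted p = 0.000634). Its CPM went from 105 with DMSO to 134 with salinomycin but from 58.7 with 5-FU to 194 with both. SLC7A11 had an interaction of 1.27 ± 0.33 and GPX4 one of -0.55 ± 0.22, neither past edgeR's test (adjusted p = 0.228 for both). The integrated stress response had a median interaction of 0.25 (camera adjusted p = 1.11e-05, and adjusted p = 0.347 with an estimated correlation). G1/S genes had one of 0.22 (camera adjusted p = 2.16e-05, and adjusted p = 0.0738 with an estimated correlation). Glycolysis and hypoxia genes had a median of -0.41 (camera adjusted p = 9.26e-06, and adjusted p = 0.347 with an estimated correlation). The mitochondrial genome had one of -0.42 (camera adjusted p = 2.25e-06, and adjusted p = 0.365 with an estimated correlation). None of the 11 lists that camera called passed with an estimated correlation. Across genes, which are not independent replicates, the interaction followed GC content with a Spearman rho of -0.690. At an unadjusted p under 0.05 edgeR's test gave 3338 genes, and at an adjusted p under 0.05 DESeq2 called 67, an unfiltered edgeR fit 1311 and a fit with an offset for GC content 29. SLC7A11 was among these 29 (0.80, adjusted p = 0.032; from 2.74e-05 to 0.491 over all settings).

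Salinomycin against 5-FU tested the difference between the single drugs. Sterol genes and histones were higher with salinomycin, and cyclin E and inflammatory genes were higher with 5-FU. INSIG1 was 4.29-fold and LSS 3.15-fold higher with salinomycin, as were PIF1 (4.72-fold) and the histone gene H2AW (7.06-fold). CCNE2 had a log2 fold change of -2.57 ± 0.26, CDKN1A one of -2.34 ± 0.23, IGF2 one of -2.34 ± 0.22 and PLAU one of -2.10 ± 0.11. Of 31 cholesterol genes 24 were higher (27 adjusted over the list alone; camera adjusted p = 1.21e-41), and of 23 host genes of small nucleolar RNAs 19 (19 adjusted over the list alone; 1.1e-27). Of 20 histones 12 were higher (14 adjusted over the list alone; camera adjusted p = 3.29e-09). Of 48 G1/S genes 34 were lower (41 adjusted over the list alone; camera adjusted p = 2.19e-29) and of 20 NF-kB genes 12 (15 adjusted over the list alone; 4.53e-13). Of 28 interferon response genes 15 were lower (17 and 1 up adjusted over the list alone; camera adjusted p = 7.41e-10). Genes of G2/M were called higher (12 higher and 2 lower; camera adjusted p = 4.7e-05) and p53 targets lower (8 lower and 3 higher; 0.0478), and neither passed with an estimated correlation (adjusted p = 0.113 and 0.134). Ribosomal protein genes had 32 of 56 higher (43 adjusted over the list alone; camera adjusted p = 4.08e-15, and adjusted p = 0.303 with an estimated correlation). One member was RPL3 at 1.19 ± 0.10. In all, camera called 16 lists here, 9 upward and 7 downward, and not all are described. edgeR's quasi-likelihood test called 3172 genes, 1476 higher and 1696 lower, so that 46.5% were higher; scaling by library totals alone gave 34.6%. Without salinomycin replicate 2 or 3 or 5-FU replicate 1 the count was 1912, 1932 or 2085, and an offset for GC content gave 5643 genes, 2750 higher and 2893 lower, which kept 3118 of these.

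Both single drugs were compared with the same 3 DMSO libraries. Of the genes called in both comparisons, 88 were higher with both drugs, 65 were lower with both and 79 went opposite ways, where independent lists would share 41.9 higher and 24.6 lower genes. CDKN1A and the cyclin E genes were among those with a rise after 5-FU but not after salinomycin, and the test between the drugs above gives that difference. CCNE2 fell with salinomycin (log2 fold change -1.25 ± 0.26, edgeR adjusted p = 0.0222). The log2 fold changes correlated across genes with a Pearson r of 0.399 and a covariance of 0.0936, or 0.298 and 0.0580 with an offset for GC content. In 20 simulations of unchanged groups against shared DMSO libraries, all drawn from the same means, r averaged 0.498 (from 0.454 to 0.527) and the covariance 0.0421 (from 0.0368 to 0.0460), and no gene was called in both comparisons. The observed r was not above the simulated one, but the simulated groups held no drug effects, which change r, so r does not decide. The observed covariance without the offset was larger than in the simulations. These used the dispersions of the fit without the offset (common coefficient of variation 0.135, or 0.079 with the offset). The covariance with the offset therefore has no matching simulation. The simulations held no GC trend common to the genes of a library. With 3 DMSO libraries the controls were too few to give each drug its own controls, so how much of the overlap comes from the shared controls was not resolved. Without DMSO replicate 1 or 2, salinomycin replicate 2 or 3 or 5-FU replicate 1 the overlap in the same direction went from 153 genes to 17, 11, 24, 20 or 65, and without DMSO replicate 3 it was 905.

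**Figure D3:**
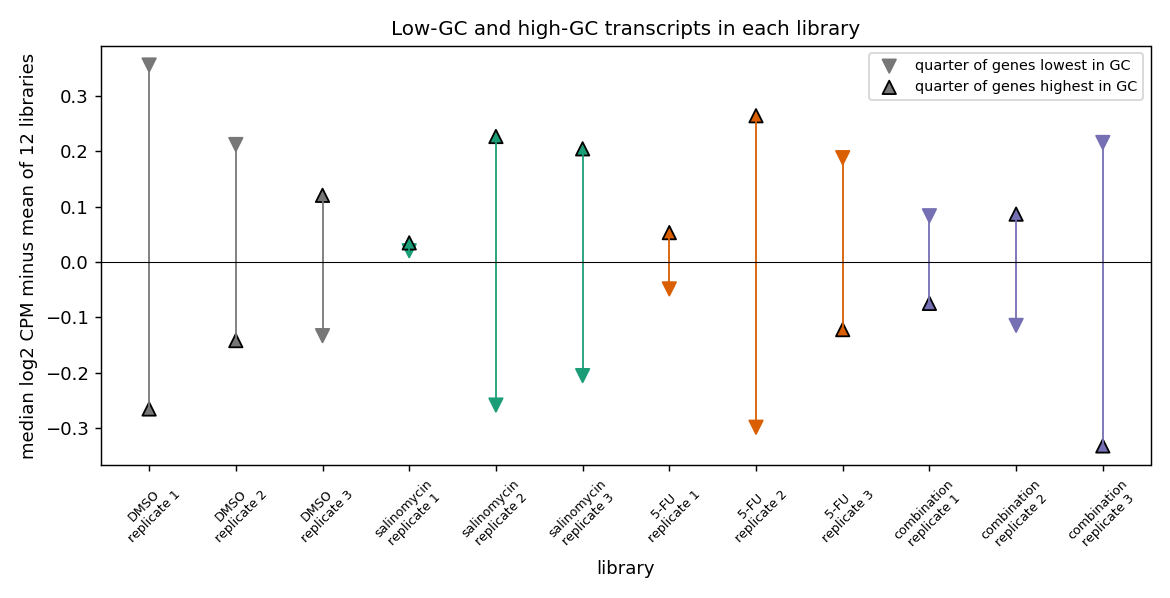
Median log2 CPM, minus the mean of the 12 libraries, of the genes with the lowest and of those with the highest GC content, for each library (horizontal, by group). The GC slopes of the DMSO, 5-FU and combination libraries lay on both sides of 0, with values from -0.298 to 0.112 per 10 points among the DMSO libraries. All salinomycin libraries had slopes above 0, from 0.00311 to 0.225.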

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

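The tests below on SLC7A11 and on the mitochondrial rRNAs were chosen only after the results had been seen. The values that drew attention are differences on the log2 scale between the effect of salinomycin with 5-FU and its effect without 5-FU. ASNS stood out as the gene past edgeR's test, at 1.38. The fixed lists that camera called for this difference had medians of -0.39 for mesenchymal genes, -0.37 for epithelial genes, 0.22 for G1/S, 0.25 for G2/M and -0.41 for glycolysis and hypoxia. The others were 0.25 for the integrated stress response, -0.20 for lysosome and autophagy, -0.42 for the mitochondrial genome, -0.29 for NRF2 targets, -0.32 for oxidative phosphorylation and -0.25 for ribosomal proteins. The GC offset ended the G2/M call (median 0.05, adjusted p = 0.584) and brought the medians to -0.26 for mesenchymal genes, -0.15 for epithelial genes, -0.24 for glycolysis and hypoxia, -0.17 for NRF2 targets, -0.14 for ribosomal proteins and -0.65 for the mitochondrial genome. It also called cholesterol genes (adjusted p = 0.000142), metallothioneins (0.00298) and the unfolded protein response (0.00996) downward. None of the 11 lists passed camera with an estimated correlation, and with a GC offset and an estimated correlation the integrated stress response was the one that passed (adjusted p = 0.00219). The ASNS call held in every setting, with values from 1.09 to 1.55 and adjusted p of at most 0.015.

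The spread between libraries of one group followed gene GC content, with a rho of 0.868 across genes, which are not independent replicates. Within 7 lists, whose members share a function, the median rho was 0.887 (from 0.795 to 0.947), which is in line with a GC bias of the libraries. The partial rho with gene length was -0.388 beside 0.869 for GC content, so a share for gene length stayed open. No biological explanation was tested for this pattern.

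The higher SLC7A11 value with both drugs than with 5-FU alone was weighed against 3 explanations. With the GC offset it was 0.813 ± 0.0968, so the GC trend that the offset fits did not account for all of it. Since it was not shown how well the offset removes a real bias, GC bias was not excluded. The other 46 members of the integrated stress response had a median of 0.425, above the range of random lists from -0.0974 to 0.0445. A joint rise of ATF4 targets predicts such a median. The SD between members was 0.820, so the members differed widely. Genes of the random lists were drawn 1 by 1, without the correlation between members, so that range may be too narrow. For salinomycin against DMSO SLC7A11 did not rise with that list (median 0.24 beside -0.34 ± 0.23 for SLC7A11). The gap was smaller with the GC offset (median 0.16 beside 0.01 ± 0.10). The other 33 NRF2 targets had a median of -0.0261, inside the range from -0.111 to 0.0642, with an SD of 0.198 between members. A joint rise of NRF2 targets of the size of the SLC7A11 change was thereby excluded, while an action of NRF2 on SLC7A11 alone was not tested.

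The mitochondrial rRNAs were lower with salinomycin than with DMSO, and lower with both drugs than with 5-FU. With the GC offset the smaller of the 2 rRNA changes was -0.740 ± 0.0906 and -0.727 ± 0.104 in these comparisons. The GC trend that the offset fits therefore did not account for the falls. How well the offset removes a real bias was not shown, so GC bias was not excluded. A loss of all mitochondrial transcripts by as much as the rRNAs was excluded for salinomycin against DMSO. The 13 mitochondrial mRNAs had a median of 0.0893 (95% bootstrap interval of the median from 0.00992 to 0.412, SD between members 0.427), or 0.216 with the GC offset. Of the 15 mitochondrial genes 3 rose and 3 fell, with the 2 rRNAs among the falls. The bootstrap treats transcripts of the same genome as independent, so its intervals may be too narrow. For the combination against 5-FU such a loss stayed open. The mRNA median was -0.317 (95% bootstrap interval of the median from -0.624 to -0.130, SD between members 0.376), or -0.417 with the GC offset. That is within 2 SE of the change of MT-RNR1 (-0.64, or -0.73 with the offset), while MT-RNR2 fell further (-1.16, or -1.27 with the offset). Lower capture of RNA without long poly(A) tails was not seen in the replication histones for salinomycin against DMSO. Their median was 0.0711 (95% bootstrap interval of the median from -0.0723 to 0.288, SD between members 0.433). It was not thereby excluded for the rRNAs, since only 20 of the 51 listed histones were measured. Histone RNA can also vary with DNA replication, whose genes fell with salinomycin. For the combination against 5-FU lower capture stayed open too, since the histones varied widely (median -0.0773, 95% bootstrap interval of the median from -0.418 to 0.328, SD between members 1.51).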

How the results depend on the processing

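The GC trend of the libraries and, with 3 libraries per group, single libraries both moved the counts of genes by more than 1.5 times; the cause was not tested further. Counts are given in the order salinomycin, 5-FU and the combination against DMSO, the combination against salinomycin and against 5-FU, the interaction, and salinomycin against 5-FU. The alternatives with GC offsets were chosen after the data had been seen. The GC offset gave 2269, 5284, 5282, 4532, 1254, 29 and 5643 genes, that offset with gene length 2300, 5499, 5556, 5021, 1674, 65 and 6118, and that offset with the replicate block 3016, 5804, 5764, 5022, 1640, 99 and 6097. Without a filter the count was 2434 for salinomycin against DMSO, 550 for the combination against 5-FU and 1311 for the interaction, and DESeq2 gave 1936, 483 and 67 there. Fits on the groups compared alone gave 380, 1511 and 1512 against DMSO and 87 for the combination against 5-FU. Limma on log2 TPM gave 308 and 1893 genes for salinomycin and 5-FU against DMSO with a pseudocount of 1, 323 and 1858 with 0.1, and without a filter 187, 1282, 1320 and 1507 for the first 4 comparisons, 3 for the interaction and 1985 for salinomycin against 5-FU. At least a 2-fold change was reached by 93, 654, 514, 427 and 54 genes in the first 5 comparisons and by 756 in the last. The replicate block gave 811, 2896, 2300, 2596, 186, 1 and 3100 genes, and 4 of 12 libraries were closest to their own number, so no pairing was assumed.

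With single libraries left out, the count ran from 109 (without DMSO 2; also 109 without salinomycin 3, 126 without salinomycin 2 and 142 without DMSO 1) to 2956 (without DMSO 3) for salinomycin against DMSO. For 5-FU it ran from 1400 (without DMSO 1; 1422 without DMSO 2, 1576 without 5-FU 2) to 3645 (without DMSO 3), and for the combination against DMSO from 1308 (without combination 1; 1349 without DMSO 2, 1503 without DMSO 1, 1534 without combination 2) to 2344 (without DMSO 3). Against salinomycin the combination ran from 1050 (without salinomycin 2; 1183 without salinomycin 3, 1222 without combination 3, 1247 without combination 1) to 2632 (without combination 2). Against 5-FU it ran from 93 (without 5-FU 1; 101 without combination 1, 125 without combination 3, 133 without 5-FU 2) to 186 (without 5-FU 3). The interaction gave 1 or 2 genes, with 2 without salinomycin 2. Salinomycin against 5-FU ran from 1912 (without salinomycin 2; 1932 without salinomycin 3, 2085 without 5-FU 1) to 2984 (without 5-FU 2).

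SLC7A11 changed sign for salinomycin against DMSO with the GC offset (0.0116), with length added (0.141) and with the block added (0.0119). For 5-FU against DMSO its adjusted p passed without a filter (-0.51, adjusted p = 0.0176), with the GC offset (-0.28) and with the block added (-0.28, adjusted p = 0.00778). For the combination against DMSO it passed with the 3 GC offsets (0.53, 0.66 and 0.53). The call against salinomycin was lost with limma (0.64, adjusted p = 0.0599; 0.92, adjusted p = 0.0713; and 0.64, adjusted p = 0.165 without a filter) and without salinomycin 2 (adjusted p = 0.167), salinomycin 3 (0.144), combination 1 (0.135) or combination 3 (0.144), with values from 0.65 to 0.97. Against 5-FU it passed without a filter (0.93), with the block (0.94, adjusted p = 0.0403), with DESeq2 (0.93) and with the GC offsets (0.81, 0.81 and 0.82). The interaction passed without a filter (1.26), with DESeq2 (1.27, adjusted p = 0.0485) and with the GC offsets (0.80, 0.67 and 0.80). For salinomycin against 5-FU it passed with the GC offsets (0.29, 0.29 and 0.30) and had the opposite sign with limma (-0.0086, -0.0029 and -0.0086) and without salinomycin 1 (-0.0164). Leaving out libraries gave ranges of -0.54 to -0.11, -0.71 to -0.30 and 0.27 to 0.64 against DMSO, 0.77 to 1.13 against 5-FU, 1.05 to 1.48 for the interaction and -0.02 to 0.37 for salinomycin against 5-FU.

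GPX4 passed for salinomycin against DMSO without a filter (0.41, adjusted p = 0.00549) and without DMSO 3 (0.56, adjusted p = 0.030), and without a filter also for the combination against salinomycin (-0.33) and the interaction (-0.56). The offset for GC and length changed its sign for 5-FU against DMSO (-0.0708), the combination against salinomycin (0.0057) and the interaction (0.0765). Its sign changed without DMSO 1 for the combination against DMSO (-0.0394; 0.24 without DMSO 3). For the combination against 5-FU it changed with the GC offsets (0.0495, 0.0943 and 0.0487) and without 5-FU 2 (0.0148; -0.23 without 5-FU 3). IFIT3 rose with 5-FU in edgeR's test but had the opposite sign with limma (-0.277, -0.191 and -0.277).

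With an estimated correlation 6, 7, 13, 8, 4, 0 and 9 lists were called, with the GC offset and an estimated correlation 7, 7, 12, 7 and 1 for salinomycin, 5-FU and the combination against DMSO, the combination against 5-FU and the interaction, and with fry 6 for the interaction. The overlap of the single drugs was 696 genes with the GC offset, 8 at a 2-fold minimum and 207 with the block. It was 11 without DMSO 2, 17 without DMSO 1, 20 without salinomycin 3, 24 without salinomycin 2, 65 without 5-FU 1 and 905 without DMSO 3. Calls of named genes stayed the same in 10177 of the checks, were lost in 1261 and turned in 3, and calls of lists stayed in 1394 and were lost in 232.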

Other observations

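Several genes outside the fixed lists moved with the drugs. The growth factor carrier FGFBP1 rose with salinomycin, and the antisense gene IGFL2-AS1 rose both with salinomycin and when salinomycin was added to 5-FU (log2 fold change 1.54 ± 0.10). In the fit with the GC offset, 29 genes had an interaction, with INHBE at 1.71, ALDH1L2 at 1.45, ASNS at 1.09, CHAC1 at 0.92 and STC2 at 0.81 larger, and the growth factor AREG at -0.92, MT-ND1 at -0.90 and PINK1 at -0.71. Keratins KRT81 and KRT17, the protease KLK10 and the cytokine IL32 were lower with both drugs than with 5-FU alone, although the KRT17 call did not hold in every fit with a library left out.

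Hypothesis: salinomycin may impose an amino acid shortage that 5-FU makes larger. When salinomycin was added to 5-FU, integrated stress response members other than SLC7A11 had a median of 0.425 (SD 0.820), against random lists from -0.0974 to 0.0445. SLC7A11 may thus have moved with ATF4 targets there. That comparison does not test whether 5-FU enlarged the response. The interaction does (list median 0.25), and with an estimated correlation the list passed only with the GC offset. 5-FU alone gave a list median of -0.16 and took ASNS from 105 to 58.7 CPM. Part of the rise thus began from a lower level. Against DMSO, 10 of 47 members of that list rose with salinomycin (adjusted p = 0.0656 with an estimated correlation) without a rise of SLC7A11 (log2 fold change -0.34, or 0.01 with the GC offset), which this hypothesis does not explain. Transport of cystine and lipid peroxides were not measured, so the RNA values do not show whether ferroptosis took place. A test would be an ATF4 knockdown with SLC7A11 measured in the combination.

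Hypothesis: salinomycin may lower sterol delivery from the lysosome, so that SREBP2 targets rise. The cholesterol list was called with the GC offset as well as without it, and the tests of the GC trend (median rho of 0.887 within lists) limit how far single values can be read. A rise of the same enzymes could also follow from a direct effect on membranes, and these data do not tell the 2 apart.

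Hypothesis: the fall of the mitochondrial rRNAs may reflect slower processing or faster loss of rRNA, because with salinomycin alone the mitochondrial mRNAs had a median of 0.0893, or 0.216 with the GC offset, beside -0.740 for the smaller rRNA change with that offset. When salinomycin was added to 5-FU the mRNAs were lower too (median -0.417 beside -0.727 with the offset), so the hypothesis rests on salinomycin alone. Lower capture of the rRNAs was not excluded there either. Salinomycin can exchange potassium across mitochondrial membranes, which could act on the mitochondrial ribosome. Labelling of newly made RNA would tell slower processing from faster loss, and another potassium ionophore would test the role of potassium.

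Regroupings of the libraries were set beside the real counts. They mix treated and control libraries, so drug effects enter the spread within the mixed groups and can lower the counts of genes. Low counts in them therefore do not exclude chance, which holds for the interaction below as well. Each comparison of 2 groups has 10 splits, too few for a share under 0.05. In 1 of the 10 splits, the real one, the genes called were 719 for salinomycin against DMSO (highest other 0), 2857 for 5-FU (1033), 2334 for the combination against DMSO (0), 2623 for the combination against salinomycin (1), 210 against 5-FU (0) and 3172 for salinomycin against 5-FU (0). The split with 1033 genes joined DMSO 1, DMSO 2 and 5-FU 3, the libraries with negative GC slopes, which points to a structure of the samples. The lists called were 15 (highest other 14), 20 (15), 22 (17), 21 (12) and 16 (13) for salinomycin, 5-FU and the combination against DMSO, the combination against 5-FU and salinomycin against 5-FU, each reached by 1 of the 10 splits. For the combination against salinomycin 2 of the 10 splits reached 15 lists. Regrouped libraries came within 1 list of the real count for salinomycin against DMSO and for the combination against salinomycin.

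For the interaction, 2 of 100 regroupings gave at least 1 gene, the real one included, and the other gave 179 genes with a GC slope contrast of 0.478, near the highest of 0.480, which points to the GC structure of the samples. At least 11 lists were called in 65 of 100 regroupings (highest 19), so the interaction lists could come from chance. The overlap of the single drugs was reached by 3 of 100 regroupings, with 1571 as the highest other, in which 5-FU libraries stood in place of DMSO, so that count points to the drug structure of the samples.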
